A study of Mus musculus with 52 samples.

How the data were processed

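RNA from sorted mouse bone marrow hematopoietic stem cells (HSCs) was measured by RNA sequencing in 52 libraries of 23 groups, spread over 7 expression tables. Libraries were made from few cells with a Smart-seq2 protocol, in which full-length cDNA is amplified and then fragmented with Tn5 transposase. All 7 deposited tables hold FPKM (fragments scaled to transcript length and to the mapped fragments of a library), per the labels and the values themselves. The submitters' processing notes list HISAT2, StringTie, featureCounts and DESeq2 and the mouse build mm10, without versions and without saying which of them made the FPKM values. Each table lists the same 24421 gene symbols, and no value column was left unmatched to a sample. FPKM sums ranged from 489832 to 602441 per library and were not a fixed total. Read counts are not part of the tables, so the depth of each library is unknown. A search for whole-read steps found no more than 4.30% of gene ratios in any bin of 0.05 log2 units. No counting interval or detection limit is therefore given, and a value of 0 means only that a gene was listed at 0.

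FPKM values were transformed as log2(FPKM + 1), without further scaling between libraries. Genes with at least 1 FPKM in at least 2 libraries of a table were tested, 10559 to 11911 per table. Every table was fitted on its own with limma 3.58.1 in R 4.3.3, with a mean for each group. Contrasts were tested with moderated statistics (eBayes with a trend in the prior variance), 2-sided, and p values were adjusted by the Benjamini-Hochberg method over the genes of a comparison. A gene was called at an adjusted p under 0.05. There were 17 comparisons, 13 between 2 groups and 4 between 2 effects (an interaction contrast). No gene was tested with limma across tables, because they could differ in normalization; the closing section sets group levels of different tables beside each other, as ratios.

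Gene groups were tested with camera from limma at an inter-gene correlation of 0.01, adjusted over the lists of a comparison, and repeated with an estimated correlation. With an estimated correlation, camera also takes its degrees of freedom from the libraries (3 to 5 residual degrees of freedom here). A list can therefore lose its call there through few libraries alone, whatever its correlation. A list needed at least 5 tested members, or 3 for embryonic globins. The 31 lists, their members, the comparisons, the tests and most alternatives were fixed before the data were examined. They covered long-term HSC identity, genes higher in aged HSCs, megakaryocyte and platelet, granulocyte and myeloid progenitor, monocyte, macrophage and dendritic cell, lymphoid priming, B cell, T cell and NK cell, and erythroid genes. Markers of mast cells, basophils and eosinophils, of stromal and endothelial cells, embryonic globins and sex-linked genes were included as well. Process lists covered S phase, G2 and M phase, immediate early response, interferon response, NF-kB and inflammatory mediators, Fc gamma receptor and ITAM signalling, IL-1 receptor signalling, and mitochondrially encoded genes. The others were nuclear oxidative phosphorylation, cytoplasmic ribosomal proteins, MYC targets and ribosome biogenesis, glycolysis and hypoxia, p53 targets, unfolded protein and integrated stress response, heat shock, cholesterol synthesis, MHC class I and II, and replication-dependent histones. Some genes are in more than 1 list.

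Named genes followed a rule. Bcl11a and Fcer1g were named whatever their p, though their values are not printed for every comparison. In each comparison, among called genes with a mean of at least 5 FPKM in the higher group and no overlap between the libraries of the compared groups, the 10 with the largest rise and the 10 with the largest fall qualified. Where no gene passed, the 5 with the smallest p in each direction were used and are described as not called. For differences between effects the overlap condition was dropped. Predicted genes were counted but not named. From each described list, up to 4 members with the smallest p were taken.

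Alternatives were a pseudocount of 0.1, no filter, quantile normalization of the log2 values, the replicate number as a block, only the 2 compared groups in the fit, and leaving out each library in turn. Added after seeing the data were a correction for GC content (a loess fit in R, per library, of each gene's deviation from its mean on the GC content of its longest transcript), crossed replicate blocks, and leaving out 2 libraries that stood apart. GC content came from GENCODE transcripts of GRCm38 (mm10), read with Python 3.11.15, as did gene positions. Figures were drawn with matplotlib 3.10.9 and numpy 2.4.6. Replicate numbers were not taken as pairs, because no labels pair the samples. The labels do not say whether replicates are separate animals, so a p value measures the spread between these samples only.

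The procedure was tested on simulated data with the spread of each table and 50 genes set at each of log2 changes of -2, -1, 1 and 2. At a change of 2 in size, 37 to 50 of 50 genes were recovered, and 4 to 16 unchanged genes were called per comparison. At a change of 1 in size, 3 to 50 of 50 were recovered, the fewest (3 and 5) in the difference between T1 and T2 effects after 5-FU. In a simulated GC trend, the correction lowered false calls from 2927 to 13 and recovered 200 of 200 changed genes. Paralogs and overlapping or antisense genes could not be separated here, since the assignment of shared reads is not stated and strand is not marked. This concerns globins, histone genes, ribosomal proteins, H2 genes, Hspa1a with Hspa1b, Ifit3 with Ifit3b, Il1bos and Airn. It also concerns named genes that lie wholly inside another gene of the same strand, which were Mir5107 (in Cd74), Mir7024 (in Nelfa), Snora74a and Fam181b.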

Results

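Messenger RNA levels were measured in HSCs of mice that differed in Bcl11a, in Fcer1g or in treatment. Bcl11a encodes a zinc-finger transcription factor, and Fcer1g encodes the common gamma chain that activating Fc receptors need for signalling. HSCs of C57BL/6 mice and of mice labelled Bcl11a KO made up the first table (C57_untreated, n = 2, and Bcl11aKO, n = 3). From the iMOS lines with Vav1-cre and Bcl11a-WT or Bcl11a-MUT (WT and MUT below), 2 HSC populations called T1 and T2 were sorted, which the labels define no further. The series asks how Bcl11a overexpression acts on wild-type HSCs beside the overexpressing cells, and places those wild-type HSCs in the T2 cells of the WT line. T1 and T2 cells of both lines were taken at 2 to 3 months (3m), at 12 months (12m) and 12 days after 1 injection of 5-fluorouracil (5-FU) at 150 mg/kg, with n = 2 in each of the 12 groups. T2 cells of both lines on a background labelled Fcer1gKO formed another table (Fcer1gKO_WT_T2 and Fcer1gKO_MUT_T2, n = 3 each). C57 and Fcer1gKO HSCs were also cultured for 24 hours with ovalbumin (OVA) or with ovalbumin immune complexes (IC): C57_IC had n = 3 and the other 3 groups n = 2. The last table held C57 HSCs after 20 days of IL-1β at 0.5 µg/day (n = 3) or of PBS (n = 3), and Fcer1gKO HSCs after IL-1β (n = 2). Mice were 2 to 3 months old in every group but those at 12 months.

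Each library had 12157 to 19667 genes above 0 and 10078 to 11655 genes at 1 FPKM or more. Replicates of a group correlated across genes at r = 0.949 or higher, the lowest value being that of 5FU_MUT_T1, whose replicate 1 had 12157 genes above 0. Genes are not independent replicates, so these correlations describe likeness only. Read depth per library is unknown. Below, a log2 fold change is given with its standard error from limma, and levels are means with SD in FPKM. Called genes per comparison are shown in a plot of their numbers.

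**Figure D1:**
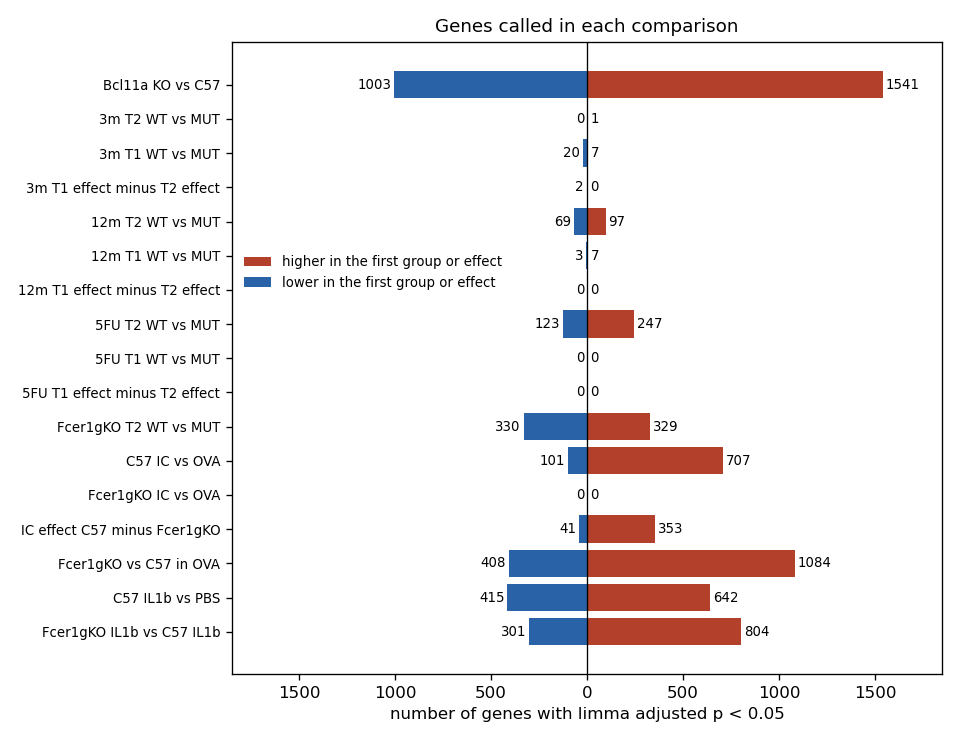
Numbers of genes called with limma in the 17 comparisons (horizontal axis, number of genes), with genes higher in the first group or effect to the right and genes lower to the left. The comparison of Bcl11aKO with C57_untreated called 1541 higher and 1003 lower genes, and 4 comparisons called 0.

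Bcl11a (chromosome 11, 24078056 to 24174123, plus strand) was detected in every library, including those labelled Bcl11a KO, where it averaged 27.7 ± 2.44 FPKM (n = 3) against 17.2 ± 0.906 FPKM in C57_untreated (n = 2). That was a rise of 0.65 ± 0.12 log2 units (adjusted p = 0.0106), opposite to what the group name says; an FPKM over the whole gene does not show whether a deleted exon was read. An exchange of the 2 group names is not excluded either, and would turn every direction of this comparison; below, the names are used as given. In T1 cells, MUT libraries had the higher means: 39.3 ± 3.01 FPKM against 26.9 ± 3.17 FPKM after 5-FU, with a WT minus MUT difference of -0.53 ± 0.14 (adjusted p = 0.434). The same T1 difference was -0.14 ± 0.07 at 12 months (adjusted p = 0.547) and -0.25 ± 0.12 at 3 months (adjusted p = 0.297), and none of the 3 was called. In T2 cells Bcl11a averaged 28.5 ± 0.297 FPKM in WT and 28.1 ± 0.892 FPKM in MUT at 12 months (adjusted p = 0.940), and 25.6 ± 1.63 FPKM against 31.9 ± 1.80 FPKM after 5-FU (-0.31 ± 0.14, adjusted p = 0.260). The T2 difference was -0.02 ± 0.12 at 3 months (adjusted p = 0.985) and 0.05 ± 0.06 in the table labelled Fcer1gKO (adjusted p = 0.686), and none of the 4 was called.

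Fcer1g (chromosome 1, 171229572 to 171234365, minus strand) was not 0 in libraries labelled Fcer1gKO. In culture with OVA it averaged 3.09 ± 0.280 FPKM in Fcer1gKO and 7.90 ± 0.747 FPKM in C57 cells, a change of -1.12 ± 0.13 (n = 2 each, adjusted p = 0.000779). After IL-1β it averaged 18.4 ± 3.07 FPKM in Fcer1gKO (n = 2) and 47.8 ± 0.724 FPKM in C57 cells (n = 3), a change of -1.34 ± 0.13 (adjusted p = 0.000254). In the iMOS lines labelled Fcer1gKO it averaged 4.80 ± 0.235 FPKM in WT and 6.29 ± 1.07 FPKM in MUT T2 cells (adjusted p = 0.168). T2 cells of the same age without that label averaged 4.83 ± 1.72 FPKM in WT and 7.06 ± 0.102 FPKM in MUT. Those cells are in a separately normalized table, and the levels were not tested against each other. A loss of Fcer1g mRNA in the iMOS lines labelled Fcer1gKO is therefore neither shown nor excluded. An FPKM over the whole gene also does not show whether a deleted exon was read.

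**Figure D2:**
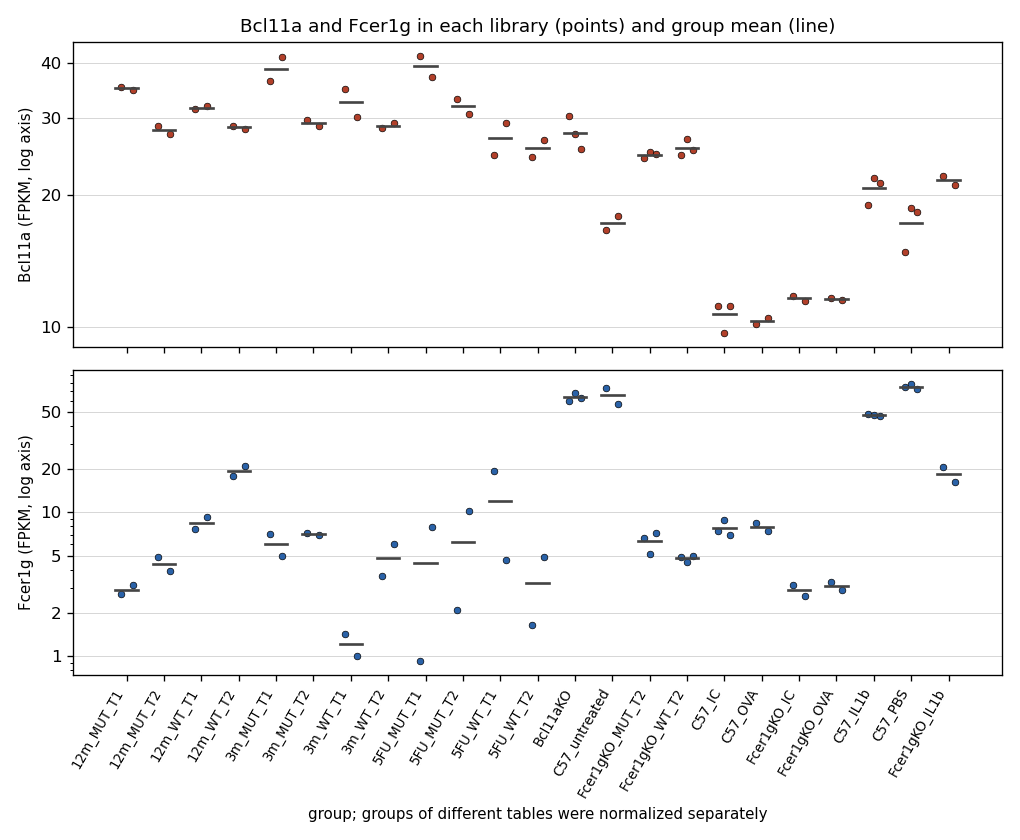
Bcl11a and Fcer1g in each library (points) and the group mean (line), in FPKM on log axes, for the 23 groups; groups of different tables were normalized separately. Bcl11a averaged 27.7 FPKM in Bcl11aKO and 17.2 FPKM in C57_untreated, and Fcer1g averaged 19.4 FPKM in 12m_WT_T2 and 4.39 FPKM in 12m_MUT_T2.

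The first comparison asked what Bcl11a does within HSCs. Genes of neutrophil granules, which store proteases and antimicrobial proteins, were lower in the libraries labelled Bcl11a KO. Elane (neutrophil elastase) averaged 9.91 ± 1.41 FPKM against 4538 ± 179.9 FPKM (-8.71 ± 0.12, adjusted p = 3.07e-07), Ctsg fell by 7.99 log2 units and Mpo (myeloperoxidase) fell by 7.18. Camp, S100a9, S100a8, Ngp, Chil3, Lcn2 and the monocyte antigen gene Ly6c2 were the other named falls, between -7.75 and -7.40. In the granulocyte and myeloid progenitor list, 22 of 22 tested members fell (22 adjusted over the list alone, median -6.59, adjusted p = 2.87e-29; adjusted p = 0.173 with an estimated correlation). B cell genes such as Vpreb1 (-5.92 ± 0.15) and Cd79a (-5.96 ± 0.18), both parts of the pre-B or B cell receptor, fell in 12 of 13 members (12 over the list alone, adjusted p = 6.65e-18; adjusted p = 0.173 with an estimated correlation). All 9 tested mast cell, basophil and eosinophil members fell as well, among them Hdc (-6.22 ± 0.24) and Cpa3 (-4.28 ± 0.18), with adjusted p = 1.73e-10 (9 over the list alone; adjusted p = 0.173 with an estimated correlation).

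Genes of stem cell identity went the other way in Bcl11aKO. In the long-term HSC list 20 of 28 members rose and 0 fell (23 and 1 adjusted over the list alone, median 1.02, adjusted p = 6.18e-09; adjusted p = 0.230 with an estimated correlation). They included the endothelial and stem cell transcription factor gene Sox18 (3.47 ± 0.18) and the adhesion gene Esam (1.77 ± 0.09). Other named rises were Erdr1 (67.4 ± 15.3 FPKM against 0.209 ± 0.165 FPKM), Klrb1c (4.62 ± 0.29), which encodes the NK1.1 receptor, Sardh, the serine protease gene Hpn (4.16 ± 0.28), Dcstamp, Lsr and the chemokine-binding receptor gene Ackr1 (3.32 ± 0.18). The adult beta globins Hbb-bt (6.50 ± 0.87, adjusted p = 0.00304) and Hbb-b2 (3.95 ± 0.92, adjusted p = 0.0241) were higher too, with Hbb-bt at 126, 937 and 149 FPKM in the KO libraries and 3.86 and 0.724 FPKM in C57_untreated. Genes of the interferon response rose in 29 of 45 members and fell in 2 (35 and 2 over the list alone, adjusted p = 6.18e-09; adjusted p = 0.241 with an estimated correlation), for example Ifi44 (1.95 ± 0.10) and Rtp4 (1.48 ± 0.14). G2 and M phase genes fell in 14 of 36 members (19 over the list alone, adjusted p = 4.09e-12; adjusted p = 0.241 with an estimated correlation), with Ube2c at -1.09 ± 0.14.

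Of 11557 genes tested, 1541 were higher and 1003 lower, and 459 and 615 of these changed at least 2-fold. Median log2 fold change over all genes was 0.13, and 0.07 after quantile normalization. C57_untreated libraries themselves carried many granulocyte transcripts: the 22 granulocyte genes made up 7.74% of their FPKM, 0.0680% in Bcl11aKO and 0.0591% in C57_PBS of another table. Mecom, a stem cell gene, averaged 26.1 FPKM in C57_untreated, 85.7 FPKM in Bcl11aKO and 54.0 FPKM in C57_PBS. Procr, another member of the long-term HSC list, averaged 19.1, 38.0 and 33.6 FPKM in the same order. RNA of other cells in C57_untreated may therefore also account for part of the rise of the long-term HSC list, which was not tested. Called genes numbered 1553 without Bcl11aKO replicate 1, 1473 without Bcl11aKO replicate 2 and 1466 without C57_untreated replicate 1. Leaving out 1 library ended the call of 1 of 20 named genes, Hbb-b2.

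At 3 months, T2 cells of the WT and MUT lines were compared, which the series did to ask about neighbours it describes as overexpressing Bcl11a. Bcl11a itself averaged 32.6 ± 3.44 FPKM in the T1 cells of the WT line and 28.8 ± 0.575 FPKM in its T2 cells (not tested). It was no higher in WT than in MUT T1 cells (38.8 ± 3.43 FPKM), so these levels show no overexpression in the WT line over the MUT line. T1 means were above T2 means in both lines, at 3 months (29.2 ± 0.559 FPKM in MUT T2), at 12 months and after 5-FU (not tested). The labels do not say what the MUT line expresses, so overexpression in T1 cells is not excluded. Only Mtmr9, a gene of the myotubularin phosphatase family, was called, higher in WT by 2.24 ± 0.19 log2 units over a MUT mean of 9.76 ± 0.312 FPKM (n = 2 each, adjusted p = 0.0261). It is also named for T1 cells, where it averaged 41.9 ± 10.6 FPKM against 10.8 ± 1.36 FPKM (1.84 ± 0.19, adjusted p = 0.0168). Among lists, cytoplasmic ribosomal proteins were higher (median 0.31, adjusted p = 1.79e-26) and cholesterol synthesis genes lower in WT (median -0.43, adjusted p = 4.46e-10), but 0 of 79 and 0 of 23 members passed the gene test. Neither was called with an estimated correlation, at 4 residual degrees of freedom (adjusted p = 0.773 for both). Dhcr7 (-1.15 ± 0.31) and Ldlr (-1.07 ± 0.32), which serve sterol synthesis and uptake, had the smallest p of the cholesterol list. Fcer1g averaged 4.83 ± 1.72 FPKM against 7.06 ± 0.102 FPKM (adjusted p = 0.905). Xist was 7.58 FPKM in 3m_WT_T2 replicate 1, with Ddx3y at 34.2 FPKM, and 0.263 to 0.539 FPKM in the other T2 libraries of that age. Whether that replicate held some RNA of the other sex was not tested. limma called 1 of 11911 genes, and 638 had an unadjusted p under 0.05. The count was 0 after quantile normalization, where Mtmr9 had an adjusted p of 0.0546 (0.272 without a filter), and 0 without 3m_MUT_T2 replicate 1 or 2 or 3m_WT_T2 replicate 1. Without 3m_WT_T2 replicate 2 another gene was called, lower in WT, so that Mtmr9 lost its call without each of the 4 T2 libraries. It was 3 without 3m_WT_T1 replicate 1, a library that stood apart by Xist (335 FPKM) and Ddx3y (0.161 FPKM).

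T1 cells of the WT line at 3 months differed in genes of cell division. The G2 and M phase list was lower than in MUT (median -0.81, adjusted p = 3.26e-19; adjusted p = 0.783 with an estimated correlation). Of its 36 members, 1 fell over all genes, the cyclin gene Ccnb1 (-1.13 ± 0.14, adjusted p = 0.0342), and 27 adjusted over the list alone, with Racgap1 at -0.73 ± 0.13. S phase genes were lower too (median -0.55, adjusted p = 6.63e-10, 0 over all genes and 17 over the list alone; adjusted p = 0.783 with an estimated correlation), with Rrm2 at -0.72 ± 0.15. The stem and progenitor antigen gene Cd34 averaged 39.4 ± 9.13 FPKM against 103 ± 15.1 FPKM (-1.37 ± 0.17, adjusted p = 0.0342), and Fcer1g averaged 1.21 ± 0.303 FPKM against 6.01 ± 1.46 FPKM (-1.65 ± 0.24, adjusted p = 0.0494). Lower as well were Rbpms2 (-2.05 ± 0.13, adjusted p = 0.00131), the histone genes Hist1h2af (-2.26 ± 0.32) and Hist1h2ad (-1.82 ± 0.26), Hbb-b2, Fgf3, Rpgrip1, Adgrl4 and Rnase6. Named rises were H2-Q9 (51.9 ± 4.33 FPKM against 16.0 ± 0.318 FPKM, adjusted p = 0.00136), a class I MHC gene, Igip, Epb4.1l4b, Hipk1 and Rictor (0.92 ± 0.12), a core part of the mTORC2 kinase complex.

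In all, 7 genes were higher and 20 lower in 3-month T1 cells of the WT line (n = 2 each). Quantile normalization ended the calls of 6 named genes, Hist1h2af, Hist1h2ad, Adgrl4, Igip, Cd34 and Fcer1g (adjusted p = 0.0507), and 14 of the 16 named genes lost the call without some library, all but H2-Q9 and Rbpms2. The count was 3 without 3m_MUT_T1 replicate 1, 3 without its replicate 2, 6 without 3m_WT_T1 replicate 1, which alone among 3-month libraries had high Xist, and 203 without 3m_WT_T1 replicate 2, the library with 19667 genes above 0. WT minus MUT effects differed between T1 and T2 for 2 of 11911 genes, both lower in T1, at the interaction contrast. Rbpms2 was 1 of them, with a difference of -2.06 ± 0.19 (adjusted p = 0.0193); the other is a predicted gene. Without 3m_MUT_T1 replicate 1 or 2 that count was 0, without 3m_WT_T1 replicate 2 it was 14, and without each of the 4 T2 libraries it was 1. The difference for Fcer1g was -1.16 ± 0.34 (adjusted p = 0.617). G2 and M phase genes differed as a list (median -0.91, adjusted p = 1.22e-24, 24 adjusted over the list alone and 0 over all genes; adjusted p = 0.826 with an estimated correlation).

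At 12 months, T2 cells of the WT line had more Fcer1g and more heat shock transcripts than those of the MUT line. Fcer1g averaged 19.4 ± 2.13 FPKM against 4.39 ± 0.682 FPKM (1.92 ± 0.15, n = 2 each, adjusted p = 0.00248). The inducible chaperone gene Hspa1a averaged 14.2 ± 2.86 FPKM against 1.16 ± 0.107 FPKM (2.80 ± 0.30, adjusted p = 0.00707). In the heat shock list 8 of 13 members rose and 0 fell (11 adjusted over the list alone, median 0.64, adjusted p = 1.35e-15; adjusted p = 0.0625 with an estimated correlation), with Hsph1 at 1.24 ± 0.13 and Hspa8 at 0.59 ± 0.08. Fc gamma receptor and ITAM signalling genes were higher as a list (adjusted p = 8.31e-05; adjusted p = 0.390 with an estimated correlation): 2 of 27 rose, Fcer1g and the Src-family kinase gene Fgr (adjusted p = 0.0106), and 5 over the list alone. Beside them, 2 of 12 members of the monocyte, macrophage and dendritic cell list rose (3 over the list alone, median 0.43, adjusted p = 0.00643; adjusted p = 0.349 with an estimated correlation), Spi1 (1.29 ± 0.13) and F13a1 (1.54 ± 0.19). At the fixed correlation that monocyte, macrophage and dendritic cell list in 12m T2 WT vs MUT had an adjusted p of 0.0683 without 12m_MUT_T2 replicate 1 and 0.555 without 12m_WT_T2 replicate 2. Genes higher in aged HSCs fell in 3 of 44 members and rose in 1 (24 and 3 over the list alone, median -0.39, adjusted p = 1.75e-09; adjusted p = 0.349 with an estimated correlation). Among them Runx1t1, a corepressor gene, averaged 2.16 ± 0.368 FPKM against 12.7 ± 2.40 FPKM (-2.11 ± 0.17, adjusted p = 0.00348).

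Other named rises in 12-month T2 cells were the nitric oxide synthase gene Nos3 (2.71 ± 0.35), Hpn (2.57 ± 0.15, adjusted p = 0.000509), the complement gene C4b (2.22 ± 0.22), Ackr1, Hbb-b2, Mirg, Fam181b and Spint1. Falls included the tight junction gene Cldn5 (24.1 ± 0.547 FPKM against 96.9 ± 4.07 FPKM, adjusted p = 5.38e-05), the hypoxia-related gene Hif3a (-1.82 ± 0.27), Npnt, Ramp2, Airn, Arpin, Ephx1 (-1.25 ± 0.12), Il17re and the collagen chaperone gene Serpinh1. Of 79 ribosomal protein genes 2, Rpl29 (-0.98 ± 0.09) and Rplp0 (-0.60 ± 0.07), fell, also 2 over the list alone; the list was lower (median -0.19, adjusted p = 4.36e-19; adjusted p = 0.483 with an estimated correlation). Of 11804 genes 97 were higher and 69 lower, 41 and 22 of them by at least 2-fold. Called genes numbered 28 without 12m_MUT_T2 replicate 1, 68 without 12m_WT_T2 replicate 1 and 92 without 12m_WT_T2 replicate 2; 7 of the 20 named genes kept the call without each library, namely Fcer1g, Hpn, C4b, Runx1t1, Cldn5, Airn and Ephx1. Quantile normalization ended the call of Mirg (adjusted p = 0.0504), and a pseudocount of 0.1 and the GC correction ended that of Npnt. Without a filter 14 of the 20 lost the call, and Hpn, Fcer1g, Runx1t1, Cldn5, Airn and Ephx1 kept it in every alternative.

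In 12-month T1 cells the same contrast called 7 higher and 3 lower genes. Higher were Hspa1a (2.91 ± 0.30, adjusted p = 0.0152), Fcer1g (8.47 ± 1.07 FPKM against 2.90 ± 0.286 FPKM, adjusted p = 0.0281) and the chaperone genes Hsph1 (1.06 ± 0.13) and Dnaja1 (0.90 ± 0.11). Lower were Cldn5 (-1.44 ± 0.08, adjusted p = 0.000644), Rpl29 (-1.18 ± 0.09) and Rplp0 (-0.70 ± 0.07). Heat shock genes rose in 3 of 13 members (7 over the list alone, adjusted p = 2.61e-09; adjusted p = 0.166 with an estimated correlation). Glycolysis and hypoxia genes were lower as a list in T1 (median -0.14, adjusted p = 3.64e-05, 0 of 22 over all genes and 2 over the list alone; adjusted p = 0.385 with an estimated correlation), with Pkm at -0.30 ± 0.06. The count of 10 became 5 without 12m_MUT_T1 replicate 1, 3 without 12m_WT_T1 replicate 1 and 2 without 12m_WT_T1 replicate 2, and all named genes but Cldn5 and Rpl29 lost the call without some library. Hsph1, Dnaja1 and Rplp0 also lost it after quantile normalization, and Hspa1a with a pseudocount of 0.1 (adjusted p = 0.0581). Without a filter 6 of the 7 named genes lost it, Rpl29 among them (adjusted p = 0.0636), so that Cldn5 alone kept it in every alternative.

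No gene differed between the T1 and T2 effects at 12 months with limma (0 of 11804, 877 at an unadjusted p under 0.05). Hpn (-1.89 ± 0.21, adjusted p = 0.0842), Cd34 (-1.53 ± 0.23), Pecam1, Sardh and Ncf2 had the smallest p of those lower in T1, and Ephx1 (1.43 ± 0.17, adjusted p = 0.113), Runx1t1 (1.79 ± 0.24), Serpine2, Mir7024 and Fstl1 of those higher. The difference for Fcer1g was -0.64 ± 0.21 (adjusted p = 0.565). G2 and M phase genes differed as a list (median -0.41, adjusted p = 3.8e-09, 0 members over all genes or the list alone; adjusted p = 0.560 with an estimated correlation). The count was 2 without 12m_MUT_T1 replicate 2, 1 without 12m_MUT_T2 replicate 1, 5 without 12m_WT_T2 replicate 1 and 1 without 12m_WT_T2 replicate 2.

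After 5-FU, which kills dividing cells and drives HSCs into cycle, ribosomal protein genes were lower in T2 cells of the WT line than of the MUT line. In that list 27 of 79 members fell and 0 rose (58 and 1 adjusted over the list alone, median -0.77, adjusted p = 2.91e-34; adjusted p = 0.856 with an estimated correlation), with Rps12 at 278 ± 77.4 FPKM against 1084 ± 128 FPKM (-1.98 ± 0.23) and Rps21 at -1.95 ± 0.21. Nuclear oxidative phosphorylation genes were higher as a list (median 0.37, adjusted p = 2.6e-05, 0 of 76 over all genes and 16 over the list alone; adjusted p = 0.856 with an estimated correlation), with Ndufa7 at 0.58 ± 0.12. Falls also included the autophagy kinase gene Ulk1 (5.38 ± 1.18 FPKM against 36.3 ± 10.6 FPKM, adjusted p = 0.0255), Csk (-2.05 ± 0.25), which encodes the kinase that restrains Src-family kinases, Prdm4, Ubqln1, Hs2st1, Atxn2, Tmem64 and Zdhhc7. Rises included the histone acetyltransferase gene Kat2a (26.9 ± 8.05 FPKM against 4.78 ± 0.640 FPKM, adjusted p = 0.0255), the endoplasmic reticulum chaperone gene Dnajb11 (1.88 ± 0.20), Sephs2 (1.59 ± 0.14), Rnaset2b, Epdr1, Vash1, Rab6a, C2cd2, Irf2bpl and Slc39a1. Fcer1g averaged 3.25 ± 2.28 FPKM against 6.17 ± 5.76 FPKM (adjusted p = 0.791).

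Of 11725 genes, 247 were higher and 123 lower (n = 2 each), but 98 and 136 after quantile normalization. The count fell to 0 without 5FU_MUT_T2 replicate 1, 0 without its replicate 2, 0 without 5FU_WT_T2 replicate 1 and 1 without 5FU_WT_T2 replicate 2, so 0 of 20 named genes kept the call without each library; it was 594 without 5FU_MUT_T1 replicate 1, the library with the fewest genes above 0. Only the 2 compared groups in the fit gave 0 called genes as well. Libraries of these 2 groups with the same replicate number deviated alike from their group means (r = 0.539 across genes). Between all groups of the 5-FU table such correlations ranged from -0.510 to 0.602, and the labels do not say what replicate numbers share. With replicate number as a block 171 genes were called.

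In T1 cells after 5-FU, limma called 0 of 11725 genes, and 1251 had an unadjusted p under 0.05. The count was 80 without 5FU_MUT_T1 replicate 2, which left the library with the fewest genes above 0 as the group's lone sample. Smallest p values belonged to Sdhaf1 (1.55 ± 0.16, adjusted p = 0.176), Slc16a1, Rnaset2b, Rfk and Nrd1 among genes higher in WT, and to P2rx1 (-2.07 ± 0.23, adjusted p = 0.176), Csk, S100a4, Cd93 (-1.22 ± 0.13) and Arpc1a among genes lower. Granulocyte genes were higher as a list (median 3.23, adjusted p = 6.15e-05, 0 of 23 members over all genes or the list alone; adjusted p = 0.941 with an estimated correlation, and 0.139 at the fixed correlation without 5FU_WT_T1 replicate 1). Their share of FPKM was 1.73% in 5FU_WT_T1, 0.290% in 5FU_MUT_T1, 0.180% in 5FU_WT_T2 and 0.401% in 5FU_MUT_T2. Fcer1g averaged 12.0 ± 10.5 FPKM against 4.41 ± 4.93 FPKM (adjusted p = 0.601).

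For the difference between T1 and T2 effects after 5-FU, limma called 0 genes, with 966 at an unadjusted p under 0.05. Grsf1 (1.94 ± 0.19, adjusted p = 0.223), Tmem248, Impad1, Mfn1 and Tpt1 had the smallest p upward, and Rbpms2 (-1.56 ± 0.26, adjusted p = 0.589), Mir17hg, Ado, Ndufaf6 and Clptm1 downward. The granulocyte list was again higher in the T1 effect (median 4.16, adjusted p = 1.37e-07; adjusted p = 0.693 with an estimated correlation). Counts were 5 without 5FU_MUT_T1 replicate 2 and 1 without 5FU_WT_T2 replicate 2.

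In the table labelled Fcer1gKO, which the series used to ask whether loss of Fcer1g rescues wild-type cells, T2 cells of the WT line had more immediate early transcripts than those of the MUT line. In that list 17 of 20 members rose and 0 fell (19 adjusted over the list alone, median 0.83, adjusted p = 3.19e-30; adjusted p = 0.00338 with an estimated correlation). Nr4a1, an orphan nuclear receptor gene, averaged 447 ± 6.10 FPKM against 87.5 ± 0.874 FPKM (2.34 ± 0.04, n = 3 each, adjusted p = 1.09e-08), and Atf3 (2.51 ± 0.14), Junb (0.84 ± 0.04) and Btg2 (1.07 ± 0.06) rose with it. Genes higher in aged HSCs rose in 18 of 35 members (29 over the list alone, median 0.55, adjusted p = 3.7e-25; adjusted p = 0.00338 with an estimated correlation), among them Clu (54.2 ± 4.41 FPKM against 16.8 ± 1.35 FPKM), Sult1a1 (1.18 ± 0.06) and Clec1a (1.14 ± 0.07). Cholesterol synthesis genes fell in 13 of 23 members (15 over the list alone, median -0.35, adjusted p = 1.84e-12; adjusted p = 0.0488 with an estimated correlation), with Fdps at -0.79 ± 0.06 and Cyp51 at -0.71 ± 0.07.

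In the MHC class I and II list 5 of 18 members rose in the same T2 cells and 1 fell (10 and 1 over the list alone, adjusted p = 3.79e-09; adjusted p = 0.0711 with an estimated correlation), and its smallest p values were those of Cd74 (1.51 ± 0.07), the invariant chain gene, and H2-Aa (1.31 ± 0.06). Heat shock genes fell in 5 of 13 members and 0 rose (8 and 1 over the list alone, adjusted p = 2.71e-05; adjusted p = 0.0587 with an estimated correlation), for example Hspa8 (-0.49 ± 0.04) and Dnaja1 (-0.57 ± 0.06). S phase genes fell in 8 of 35 members (12 over the list alone, adjusted p = 4.17e-07; adjusted p = 0.240 with an estimated correlation), with Mcm2 at -0.33 ± 0.06. For p53 targets the mean was 0.23 and the median -0.01, opposite in sign; the list was called up (adjusted p = 0.0122, 6 of 22 rose, 7 over the list alone; adjusted p = 0.124 with an estimated correlation), and it shares Btg2 with the immediate early list. Cdkn1a, which encodes the cell cycle inhibitor p21, was at 1.36 ± 0.06.

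Remaining named rises were the matricellular gene Cyr61 (2.53 ± 0.11), Mir5107, which lies inside Cd74 on the same strand so that its reads cannot be separated from those of Cd74, Id3 (1.93 ± 0.23), Mir22hg, Skil and Smad7 (1.59 ± 0.08), the last 2 both feedback regulators of TGF-beta signalling, and Cldn5 (1.68 ± 0.26, adjusted p = 0.00726). Remaining falls were Hist2h2aa2 (-3.17 ± 0.12), Erdr1 (27.5 ± 2.23 FPKM against 111 ± 5.48 FPKM), the carbonic anhydrase gene Car1, Fcna, the homing receptor gene Sell (-1.27 ± 0.10), the complement gene C1qc, Ablim1, BC037034, Gt(ROSA)26Sor and Hspa1a. Of 11478 genes 329 were higher and 330 lower, 58 and 12 by at least 2-fold, and the split was 409 and 269 after quantile normalization. Called genes numbered 417 without Fcer1gKO_MUT_T2 replicate 1, 389 without its replicate 2, and 390, 411 and 269 without Fcer1gKO_WT_T2 replicates 1, 2 and 3. Car1 and Hspa1a lost the call without some library, and Hspa1a with a pseudocount of 0.1. All 6 libraries showed both Xist (47.7 to 73.2 FPKM) and Ddx3y (9.26 to 22.9 FPKM). Ddx3y did not overlap between the lines, at 9.26, 15.1 and 12.6 FPKM in MUT and 17.0, 22.9 and 17.1 FPKM in WT. An even mix of sexes in the 2 lines is therefore not shown, and its part in the called genes was not tested.

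Culture with immune complexes asked what Fc gamma receptor activation does to HSCs. In C57 cells, interferon response genes were higher with IC than with OVA: 42 of 46 members rose and 0 fell (44 adjusted over the list alone, median 0.61, adjusted p = 8.53e-41; adjusted p = 0.00603 with an estimated correlation). Rtp4 (1.10 ± 0.04), Oas3 (1.12 ± 0.05), Isg15 (1.41 ± 0.08) and Irf7 (1.54 ± 0.06, adjusted p = 7.82e-06), the transcription factor gene that amplifies type I interferon, had the smallest p. The 10 named rises lay outside that list: Chchd10 (33.1 ± 8.35 FPKM against 2.10 ± 0.619 FPKM), Prkcdbp (3.26 ± 0.24), Rsrp1, the citrate carrier gene Slc25a1 (143 ± 21.1 FPKM against 15.4 ± 4.81 FPKM, adjusted p = 0.000182), H13, Hist2h3c2, Pgls, the ferredoxin gene Fdx1, Ndfip1 and the translation factor gene Eif5. Lower were Scin (-1.09 ± 0.18), the platelet chemokine gene Pf4 (117 ± 19.6 FPKM against 212 ± 1.24 FPKM), Csf2rb (-0.81 ± 0.08), which encodes the shared beta chain of the IL-3, IL-5 and GM-CSF receptors, Cd96, Ier3, Neurl3, Nqo1, Nt5dc2, Myl10 and Eif3j2. Cytoplasmic ribosomal proteins were lower as a list (median -0.16, adjusted p = 2.15e-18, 0 of 79 over all genes or the list alone; adjusted p = 0.568 with an estimated correlation).

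C57 cells had 707 higher and 101 lower genes with IC (n = 3 against 2), 164 and 2 by at least 2-fold; the split was 554 and 201 after quantile normalization. Counts were 1749 without C57_IC replicate 1, 410 without C57_OVA replicate 1 and 373 without C57_OVA replicate 2, and 5 of 20 named genes lost the call without some library: Ndfip1, Scin, Nt5dc2, Myl10 and Eif3j2. In Fcer1gKO cells limma called 0 of 10559 genes with IC (n = 2 each, 390 at an unadjusted p under 0.05), and 2 and 1 without Fcer1gKO_OVA replicate 1 or 2. Smallest p values there were those of Plscr1 (0.29 ± 0.04, adjusted p = 0.700), Plscr2, Nfkb2, Ttc8 and Matk upward and Atp6v0c (-0.51 ± 0.06, adjusted p = 0.280), Samd10, Hs3st1, Skil and Rtp4 (-0.25 ± 0.04) downward. The interferon list was lower with IC in Fcer1gKO cells (median -0.10, adjusted p = 1.24e-12), with 0 members over all genes and 1 over the list alone; adjusted p = 0.0918 with an estimated correlation.

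IC effects differed between the genotypes for 394 genes, 353 higher and 41 lower in C57, at the interaction contrast. Genotype and sex were fully confounded in the culture libraries, so these differences cannot be assigned to Fcer1g genotype alone. Interferon genes accounted for 35 of 46 list members higher and 0 lower (43 over the list alone, median 0.72, adjusted p = 3.74e-43; adjusted p = 0.00526 with an estimated correlation), with Irf7 at 1.77 ± 0.09. Rsrp1 (4.53 ± 0.63), Chchd10 (4.27 ± 0.43), Ndfip1, Fdx1, Eif5, Hgh1, Slc25a1, Hist2h3c2, Prkcdbp and H13 were the named genes with a positive difference. Some of them differed widely between the Fcer1gKO_OVA libraries, as Rsrp1 (114 and 36.5 FPKM), Ndfip1 (12.1 and 2.63 FPKM) and Eif5 (45.2 and 16.1 FPKM). H13 differed less (172 and 131 FPKM). Scin (-1.79 ± 0.26), Cd96, Ier3, Csf2rb (-1.08 ± 0.12) and its paralog Csf2rb2, Neurl3, Snora74a, Plscr2, Serpinb10 and Nqo1 were those with a negative one. The number was 1049 without C57_IC replicate 1, 255 and 207 without C57_OVA replicates 1 and 2, 178 without Fcer1gKO_IC replicate 1 and 209 without Fcer1gKO_OVA replicate 1; Ndfip1, Snora74a and Serpinb10 lost the call without some library.

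The genotypes already differed with OVA alone. Interferon genes were higher in Fcer1gKO cells, 45 of 46 over all genes and over the list alone (mean 1.33, adjusted p = 2.97e-48; adjusted p = 0.00400 with an estimated correlation). Irf7 averaged 169 ± 1.99 FPKM against 25.5 ± 1.05 FPKM and Ifit3 averaged 59.9 ± 2.42 FPKM against 6.83 ± 3.10 FPKM, with its paralog Ifit3b at 2.83 ± 0.25. The list's mean log2(FPKM + 1) was 4.39 and 4.33 in the C57_OVA libraries, 5.05 to 5.11 in C57_IC, 5.67 and 5.72 in Fcer1gKO_OVA and 5.57 and 5.61 in Fcer1gKO_IC. Megakaryocyte and platelet genes rose in 10 of 18 members (14 over the list alone, adjusted p = 8.52e-07; adjusted p = 0.171 with an estimated correlation), with the P-selectin gene Selp at 1.28 ± 0.08. Ribosomal protein genes fell in 50 of 79 members (68 over the list alone, adjusted p = 1.13e-26; adjusted p = 0.171 with an estimated correlation), for example Rpl35a at -0.30 ± 0.05.

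**Figure D3:**
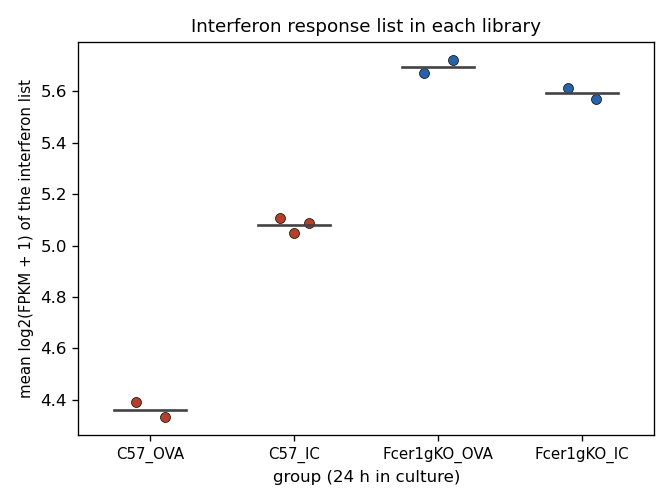
Mean log2(FPKM + 1) of the 46 interferon response genes (vertical axis) in each library of the 4 culture groups (points). The 2 C57_OVA libraries sit at 4.33 and 4.39, below the other 7 libraries, which sit between 5.05 and 5.72.

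Other rises in Fcer1gKO_OVA were H13, Chchd10 (2.97 ± 0.32), Pgls, Prkcdbp, Slc25a1 and Fdx1, all 6 also named among the rises with IC in C57. Both comparisons use the C57_OVA libraries: 604 genes were called the same way in both (76.5 for independent calls), and r across genes was 0.799, where sharing alone gave a mean of 0.549 in simulations. Falls included Scin (-1.74 ± 0.19), the granzyme gene Gzmb (-1.39 ± 0.21), Man1a, Mtmr1, Vps37a, Atxn2, Atp11b and Kctd3, and the last 6 lost the call without some library. Sex-linked transcripts separated the genotypes: Xist averaged 62.9 ± 4.22 FPKM against 1.28 ± 0.371 FPKM, the Y-linked Ddx3y changed by -4.19 ± 0.12 and Eif2s3y by -4.68 ± 0.11. Genotype and sex are therefore fully confounded in the 9 culture libraries. Of 10559 genes 1084 were higher and 408 lower, 800 and 735 after quantile normalization. Called genes numbered 634 and 606 without C57_OVA replicates 1 and 2, and 494 and 922 without Fcer1gKO_OVA replicates 1 and 2.

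IL-1β given to C57 mice for 20 days was accompanied by changes in lineage and cell cycle genes. G2 and M phase genes rose in 23 of 36 members (32 adjusted over the list alone, median 0.49, adjusted p = 3.95e-17; adjusted p = 0.139 with an estimated correlation), with Ccnb1 at 0.98 ± 0.12 and Aurka at 1.17 ± 0.16. Megakaryocyte and platelet genes rose in 8 of 20 members and fell in 2 (13 and 2 over the list alone, adjusted p = 4.2e-05; adjusted p = 0.297 with an estimated correlation), among them Selp (2.13 ± 0.15) and the thrombin receptor gene F2rl2 (1.74 ± 0.16). Cholesterol synthesis genes rose in 11 of 23 members (14 over the list alone, adjusted p = 7.85e-09; adjusted p = 0.139 with an estimated correlation), with Msmo1 at 1.78 ± 0.11 and Ldlr at 1.75 ± 0.17. In the MHC list 5 of 17 members fell and 1 rose (7 and 2 over the list alone, adjusted p = 0.00104; adjusted p = 0.139 with an estimated correlation); Cd74 averaged 21.0 ± 0.948 FPKM against 123 ± 19.8 FPKM and H2-Aa 23.6 ± 1.01 FPKM against 99.2 ± 7.65 FPKM. Ribosomal protein genes fell in 11 of 79 members (43 over the list alone, adjusted p = 6.93e-20; adjusted p = 0.311 with an estimated correlation), with Rps13 at -0.63 ± 0.14. Lymphoid priming genes rose in 7 of 14 and fell in 1 (7 and 1 over the list alone, adjusted p = 6.09e-05; adjusted p = 0.230 with an estimated correlation), with Wfdc17 at 186 ± 31.5 FPKM against 17.1 ± 2.34 FPKM.

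Beside Wfdc17, named rises were the tetraspanin gene Cd53 (94.9 ± 9.51 FPKM against 7.09 ± 0.189 FPKM, adjusted p = 2.9e-09), Fcer1a, which encodes the IgE-binding chain of the high-affinity IgE receptor, Ms4a3 (2.95 ± 0.12), a marker of granulocyte and monocyte progenitors, Oosp1, Wfdc18, Tmem215, the lipoprotein receptor gene Vldlr (2.34 ± 0.15), Pcp4l1 and Hbb-bt. Beside Cd74 and H2-Aa, named falls were the retinoic acid hydroxylase gene Cyp26b1 (-2.43 ± 0.17), Sult1a1 (43.4 ± 2.81 FPKM against 224 ± 2.70 FPKM, adjusted p = 3.98e-08), Car1, Serpina3f, Hif3a, Airn and Tmem158. Hba-a1 also qualified by the rule (-4.35 ± 1.26, adjusted p = 0.0482), but its PBS libraries had 186, 0.0223 and 43.7 FPKM, and it lost the call with a pseudocount of 0.1, after quantile normalization and after the GC correction. Fcer1g averaged 47.8 ± 0.724 FPKM against 74.8 ± 3.03 FPKM (-0.64 ± 0.12, n = 3 each, adjusted p = 0.00404). Of 11312 genes 642 were higher and 415 lower, 126 and 73 by at least 2-fold, and fold changes correlated with GC content across genes at r = -0.251. Counts were 551, 597 and 581 without C57_IL1b replicates 1, 2 and 3.

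The last comparison asked whether Fcer1g deficiency lessens the effect of IL-1β. Fcer1gKO HSCs (n = 2) had fewer cholesterol pathway transcripts than C57 HSCs (n = 3) after IL-1β: 9 of 23 members fell and 0 rose (16 adjusted over the list alone, median -0.50, adjusted p = 7.37e-09; adjusted p = 0.171 with an estimated correlation), with Ldlr, the LDL receptor gene, at 3.65 ± 1.70 FPKM against 17.0 ± 1.38 FPKM and Fdps at -0.95 ± 0.14. G2 and M phase genes rose in 9 of 36 members (15 over the list alone, adjusted p = 2.04e-05; adjusted p = 0.498 with an estimated correlation), with Nusap1 at 0.79 ± 0.14. Oxidative phosphorylation genes fell in 8 of 76 members (31 down and 2 up over the list alone, adjusted p = 1e-07; adjusted p = 0.498 with an estimated correlation), with Ndufc1 at -0.60 ± 0.16. After the GC correction these 3 lists were still called at the fixed correlation, with adjusted p of 1.89e-11, 0.000764 and 1.33e-08.

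Higher in Fcer1gKO were Xlr3b (1.69 ± 0.17), the sulfotransferase gene Sult1a1 (138 ± 8.28 FPKM against 43.4 ± 2.81 FPKM, adjusted p = 5.04e-05), Hif3a (1.63 ± 0.16), Tmem158, the interferon-inducible GTPase gene Iigp1 (1.26 ± 0.14), Serpina3f, the Rh-associated glycoprotein gene Rhag, Trim59, Il1bos and Rnft1. Lower were the chaperone gene Hspa1b (0.546 ± 0.193 FPKM against 6.16 ± 0.630 FPKM, adjusted p = 0.000254), Fcer1g, Wfdc18 (-1.18 ± 0.23), Lst1, Ppp6r1, Anapc13, Hmga1 and the histone genes Hist1h2bf and Hist1h2be. Of 11312 genes 804 were higher and 301 lower (674 and 424 after quantile normalization), 34 and 18 by at least 2-fold. Fold changes correlated with GC content across genes at r = -0.505, and 341 genes were called after the GC correction (178 higher and 163 lower), 261 of them among the 1105; Hmga1 then had an adjusted p of 0.0937. Counts were 470, 313 and 254 without C57_IL1b replicates 1, 2 and 3, and 355 and 205 without Fcer1gKO_IL1b replicates 1 and 2; 7 of 20 named genes lost the call without some library, Il1bos, Hist1h2bf, Wfdc18, Hmga1, Lst1, Anapc13 and Hist1h2be.

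Some genes called with IL-1β in C57 moved the other way in Fcer1gKO. There were 77, of which 34 rose with IL-1β and were lower in Fcer1gKO, and 43 the reverse; independent calls would give 46.6. Another 108 moved the same way (56.7 if independent). Across genes the 2 fold changes correlated at r = 0.0853, although the shared C57_IL1b libraries alone gave a mean r of -0.446 in 100 simulations of unchanged groups. After the GC correction 58 opposite and 29 same-direction genes were called (14.5 opposite if independent). The opposite count was 46, 35 and 36 without C57_IL1b replicates 1, 2 and 3, and 42 and 35 without Fcer1gKO_IL1b replicates 1 and 2.

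T2 effects of the 4 tables shared few genes. Over the 6 pairs of tables, 17 calls in the same direction were shared, against 17.5 for independent calls. That sum mixes unlike pairs. The 3-month T2 comparison called 1 gene, so its pairs could hardly share any (0.00799 to 0.0286 for independent calls). T2 calls after 5-FU shared 0 genes with 12 months (2.65 for independent calls) and 7 with the table labelled Fcer1gKO (10.4 for independent calls). At 12 months and in the table labelled Fcer1gKO, 10 genes were shared (4.37 for independent calls), among them Plscr2, Gdf15, Rbpms2 and Zfp36, which were chosen after their values were seen. Shared calls numbered 8 without 12m_MUT_T2 replicate 1, 26 without its replicate 2 and 10 without 12m_WT_T2 replicate 1. They numbered 10 without either 5FU_MUT_T2 library, 10 and 11 without 5FU_WT_T2 replicates 1 and 2, 9 without Fcer1gKO_MUT_T2 replicate 1, and 10 and 6 without Fcer1gKO_WT_T2 replicates 2 and 3.

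Across all comparisons, 151 list tests were called at the fixed correlation and 6 with an estimated one. The 6 were interferon response in the C57 IC effect, its difference between genotypes and the OVA genotype comparison, and immediate early, aged HSC and cholesterol genes in the T2 cells labelled Fcer1gKO. At the fixed correlation, ribosomal proteins were called in 13 of 17 comparisons, S phase, G2 and M phase and oxidative phosphorylation in 11 each, interferon response in 9, and cholesterol synthesis in 8. Aged HSC genes, monocyte, macrophage and dendritic cell genes, MYC targets and replication-dependent histones were called in 7 each. Megakaryocyte, granulocyte, immediate early, NF-kB, heat shock and MHC lists were called in 6 each, Fc gamma receptor genes in 5, lymphoid priming in 4 and the unfolded protein response in 3. Long-term HSC, glycolysis and IL-1 receptor signalling genes were called in 2 each, the last up in the 12-month T2 effect (adjusted p = 0.0187) and down in the T1 minus T2 difference (adjusted p = 0.0214). B cell genes were called in 2 of 6, mast cell, basophil and eosinophil genes in 1 of 4, and T and NK cell (smallest adjusted p = 0.0376), erythroid (0.0389) and p53 target genes in 1 each. Stromal and endothelial genes were called in 0 of 17 by camera (smallest adjusted p = 0.121), and sex-linked genes in 0 of 16 (smallest adjusted p = 0.0826), although 3 of 8 rose and 4 fell between the OVA genotypes. Embryonic globins had too few tested members, and 0 of 13 mitochondrially encoded genes were listed.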

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

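The tests of granulocyte RNA, loss of Bcl11a, exchanged group names, GC content, Fcer1g genotype, library variation, sex and immune complexes were chosen or worded after the results were seen; the shared-library test and the counts of other splits were set before theirs. For sex, for immune complexes and for GC content the bounds were rewritten after their values were known, and the reading of the genotype test was settled after its value.

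Effects of the WT against the MUT line differed between T1 and T2 cells at 3 months for 2 genes, by the test of the difference itself; Rbpms2 differed by -2.06 log2 units. IC effects differed between C57 and Fcer1gKO cells for 394 genes by the same kind of test. Genotype and sex were fully confounded in those libraries, so the 394 cannot be assigned to Fcer1g genotype alone. Log2 differences were 4.53 for Rsrp1, 4.27 for Chchd10, 4.19 for Ndfip1, 4.02 for Fdx1, 3.98 for Eif5, 3.81 for Hgh1, 3.81 for Slc25a1, 3.78 for Hist2h3c2, 3.75 for Prkcdbp and 3.68 for H13. On the other side were Scin at -1.79, Cd96 at -1.28, Ier3 at -1.18, Csf2rb at -1.08, Neurl3 at -1.07, Csf2rb2 at -1.06, Snora74a at -1.05, Plscr2 at -0.99, Serpinb10 at -0.98 and Nqo1 at -0.96. Without C57_IC replicate 1 the count was 1049, without C57_OVA replicates 1 and 2 it was 255 and 207, without Fcer1gKO_IC replicate 1 it was 178 and without Fcer1gKO_OVA replicate 1 it was 209. Without 3m_MUT_T1 replicate 1 or 2 the 3-month count was 0, without 3m_WT_T2 or 3m_MUT_T2 libraries 1 each, and without 3m_WT_T1 replicate 2 it was 14.

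Granulocyte genes were lower in Bcl11aKO than in C57_untreated. With the group names as given, the other C57 group stood against a fall through loss of Bcl11a. Over the 22 genes the median ratio of C57_PBS to Bcl11aKO was 0.601, where such a fall needed 4 or more. C57_PBS was not a like control, though. It had 20 days of PBS, with Xist at 0.111 to 0.213 FPKM and Ddx3y at 45.0 to 59.2 FPKM. Xist was 159 to 197 FPKM in Bcl11aKO and 124 and 170 FPKM in C57_untreated. Ddx3y was 0 FPKM in both, so sex differed as well. RNA of other cells in the C57_untreated libraries may account for the pattern, as the median ratio of C57_untreated to C57_PBS was 209 (both ratios set separately normalized tables beside each other), with Ngp at 17233 FPKM, S100a9 at 5382 FPKM and Elane at 4538 FPKM. B cell genes (Cd79a at 94.1 FPKM) were high in the same libraries although the cells were sorted as HSCs. Labels give an age of 2 to 3 months for Bcl11aKO, C57_untreated and C57_PBS alike, and handling was not tested. An exchange of the names would turn the pattern and the test of loss around. Bcl11a spoke for it (higher in Bcl11aKO by 0.65 log2 units) and against it (17.2 FPKM in both C57_untreated and C57_PBS). Mecom in C57_PBS (54.0 FPKM) lay between Bcl11aKO (85.7 FPKM) and C57_untreated (26.1 FPKM). As with granulocyte genes, C57_PBS was nearer to Bcl11aKO than to C57_untreated in Cd79a (0.206, 0.510 and 94.1 FPKM). An exchange and RNA of other cells would both give that. The exchange stays open because FPKM does not show a deleted exon.

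Opposite changes with IL-1β and in Fcer1gKO numbered 77 genes, and 58 after the GC correction, against 14.5 for independent calls, a number that leaves out the shared libraries. GC content was excluded as the whole cause, since 48 of the 77 kept both calls after the correction. Shared libraries remain open for part of the pattern: the covariance of all fold changes was 0.0106, above the simulated range of -0.0147 to -0.0115, so across all genes the fold changes did not oppose each other more than sharing alone gives. Fcer1g genotype may alter the response to IL-1β, but the covariance after the GC correction was -0.00418 and that table holds no Fcer1gKO group without IL-1β, so that genotype and response cannot be told apart. The count was 46, 35 and 36 without C57_IL1b replicates 1, 2 and 3, and 42 and 35 without Fcer1gKO_IL1b replicates 1 and 2.

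Interferon genes were lower in C57_OVA than in the other culture groups. For the interferon list, the largest range between libraries within another group was 8.30% of the C57 difference. That argues against variation between single libraries of a group. It cannot exclude a shift shared by both C57_OVA libraries, since replicates may not be separate animals or cultures. For 665 other genes higher with IC, variation between libraries stays open, because their share of 20.4% follows from picking them by their call. Sex was excluded for the difference within C57, as Xist reached at most 1.54 FPKM in the 5 C57 libraries and Ddx3y was 20.9 to 25.3 FPKM. A response to immune complexes may explain it, with an IC effect in Fcer1gKO of -14.4% of that in C57, but Fcer1gKO cells were already at 185% of the C57 difference with OVA, and the other genes at 97.0%. Something particular to the C57_OVA cultures therefore cannot be told apart from a response, since their 2 libraries are the only C57 control.

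Of the 10 splits of the 6 T2 libraries labelled Fcer1gKO, 1 called as many genes as the real one (659), the real one itself, and the highest other called 1. For IL-1β in C57 the same count was 1 of 10, with 1057 genes in the real split and 2 in the highest other. Splits numbering 10 are too few for a share under 0.05.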

How the results depend on the processing

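The GC correction, the crossed replicate blocks, the alternatives for the overlap of T2 effects and the opposite IL-1β genes, and leaving out 2 libraries of groups not compared were chosen after seeing the data; the other alternatives were planned. No gene result with a call in the main fit or the alternative changed direction. Over all alternatives 2642 gene results kept their side of the threshold, 446 lost the call and 6 gained it. Among the 2642, results not called in either fit could change sign and were still counted as kept. Of list results 1535 kept direction and call, 298 lost the call and 11 reversed. Counts stayed within 1.5 times in 120 cases and moved further in 114. Where 1 library was left in a group, it was assumed to vary like the other groups. Depth is unknown, so no limit from it can be given.

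Without a filter more low genes were tested, and called genes numbered 6 in 3-month T1, 35 in 12-month T2, 5 in 12-month T1, 2 in 5-FU T2, 342 in T2 labelled Fcer1gKO, 513 in C57 IC, 2 in Fcer1gKO IC, 194 in the IC interaction, 938 between OVA genotypes, 675 in C57 IL-1β and 244 in Fcer1gKO IL-1β; shared T2 calls numbered 2 and opposite IL-1β genes 30. Named genes that lost the call without a filter numbered 1 of 20 in Bcl11aKO, 1 of 1 in 3-month T2, 14 of 16 in 3-month T1, 1 of 1 in their difference, 14 of 20 in 12-month T2, 6 of 7 in 12-month T1, 20 of 20 in 5-FU T2 and 4 of 20 in T2 labelled Fcer1gKO. They numbered 3 of 20 in C57 IC, 6 of 20 in the IC interaction and between OVA genotypes, 1 of 20 in C57 IL-1β and 8 of 20 in Fcer1gKO IL-1β. With replicate number as a block they were 1383 in Bcl11aKO, 8 in 3-month T1, 1 in its difference from T2, 6 in 12-month T1, 171 in 5-FU T2, 505 in C57 IC, 230 in the IC interaction, 482 in Fcer1gKO IL-1β and 47 opposite genes. Crossed blocks gave 185 in 3-month T1 and 21 in 5-FU T1. With the 2 compared groups alone the numbers were 6 and 11 in 3-month T2 and T1, 50 and 6 in 12-month T2 and T1, 0 in 5-FU T2 and 1917 in Fcer1gKO IL-1β. Quantile normalization gave 0 in 3-month T2 and 234 in 5-FU T2, a pseudocount of 0.1 gave 1 in each T1 minus T2 difference at 3 and 12 months, and the GC correction gave 341 in Fcer1gKO IL-1β. With an estimated correlation 6 of 151 list calls remained. That test had only 3 to 5 residual degrees of freedom, so the losses cannot be laid to correlation between genes. Apart from the filter and the smaller sets of samples, the cause was not tested.

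Leaving out each library gave 1466 to 2051 in Bcl11aKO, 0 to 3 in 3-month T2, 3 to 203 in 3-month T1, 0 to 14 in their difference, 28 to 131 in 12-month T2, 2 to 10 in 12-month T1 and 0 to 5 in their difference. The ranges were 0 to 594 in 5-FU T2, 0 to 80 in 5-FU T1, 0 to 5 in their difference, 269 to 636 in T2 labelled Fcer1gKO, 373 to 1749 in C57 IC, 0 to 2 in Fcer1gKO IC and 178 to 1049 in the IC interaction. They were 494 to 922 between OVA genotypes, 551 to 1119 in C57 IL-1β, 205 to 470 in Fcer1gKO IL-1β, 35 to 106 for opposite genes and 6 to 26 for shared T2 calls.

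List tests that reversed follow as median log2 changes, with the opposite end of the range when a library was left out. They were 0.0393 for heat shock in 3-month T2 without 3m_MUT_T2 replicate 1 (lowest -0.532), and for oxidative phosphorylation in 3-month T1 0.0072 without 3m_MUT_T1 replicate 1 and 0.0586 without 3m_WT_T1 replicate 1 (lowest -0.312). Ribosomal proteins reversed to -0.0168 in 3-month T1 without 3m_WT_T1 replicate 2 (highest 0.326), and in its difference from T2 to 0.00144 with quantile normalization, 0.00438 without 3m_MUT_T1 replicate 1 and 0.0326 without 3m_WT_T1 replicate 1 (lowest -0.296). G2 and M phase reversed to 0.124 in 12-month T1 without 12m_WT_T1 replicate 2 (lowest -0.347), and S phase to 0.078 in 5-FU T1 without 5FU_MUT_T1 replicate 1 (lowest -0.547). Immediate early genes reversed to -0.00786 in the 5-FU difference without 5FU_WT_T2 replicate 1 (highest 1.33), and B cell genes to -0.0299 in C57 IL-1β without a filter. The cause was not tested.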

Other observations

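The overlap of opposite T2 changes was tested only after the shared genes had been seen. Between 12-month T2 cells and T2 cells labelled Fcer1gKO, 33 genes were called in opposite directions, against 4.37 for independent calls. Of these, 19 were higher in the WT line at 12 months and lower in the cells labelled Fcer1gKO, among them the chaperone genes Hspa8 (0.59 ± 0.08 and -0.49 ± 0.04), Hsph1 (1.24 ± 0.13 and -0.69 ± 0.08) and Dnaja1 (0.81 ± 0.11 and -0.57 ± 0.06), and the progenitor antigen gene Cd34 (1.12 ± 0.16 and -0.30 ± 0.06). The other 14 went the other way, with Cldn5 at -1.96 ± 0.08 and 1.68 ± 0.26, and the surface enzyme gene Cd38 at -0.57 ± 0.11 and 0.88 ± 0.13. These genes were chosen after their values were seen. Across genes the effects correlated at r = -0.148, and genes are not independent replicates. Age, the Fcer1g label (Fcer1g averaged 4.80 ± 0.235 and 6.29 ± 1.07 FPKM with it, against 4.83 ± 1.72 and 7.06 ± 0.102 FPKM in 3-month T2 cells without it) and table all differ between the 2 comparisons, and their difference was not tested.

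Genes of the Fc receptor list also changed outside the Fcer1g comparisons. In Bcl11aKO, Fcgr3 (-5.43 ± 0.15) and Fcgr2b (-3.53 ± 0.17), which encode Fc gamma receptors, fell beside the granulocyte genes; 8 of 34 list members fell and 2 rose (10 and 2 adjusted over the list alone, adjusted p = 3.1e-05; adjusted p = 0.241 with an estimated correlation). RNA of other cells in C57_untreated and an exchange of the group names stay open for these falls, as for the granulocyte genes. They cannot be assigned to loss of Bcl11a. With IL-1β in C57, Fcgr2b (1.07 ± 0.15) and the adaptor gene Lat2 (1.12 ± 0.13) rose while Fcer1g fell (-0.64 ± 0.12). That list was called up (adjusted p = 0.0252; adjusted p = 0.311 with an estimated correlation), and at the fixed correlation it had an adjusted p of 0.0724 without C57_IL1b replicate 2 and 0.107 without C57_PBS replicate 2.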
